A study of Mus musculus with 6 samples.

How the data were processed

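Total RNA of mouse ES cells given a scrambled control siRNA or an siRNA against BRG1 was profiled on 6 single-colour Agilent arrays, 3 per group, and each array was assigned to its group from the sample labels. Per the labels' protocols, the siRNA treatment lasted 48 h, RNA was extracted, treated with DNase and purified with a kit, and Cy3-labelled cRNA was made from 500 ng. The deposited scanner files hold linear spot intensity: per the file headers, the authors used Agilent Feature Extraction 9.5.3.1 on array design 014868, and per the submitters' processing notes the version was 9.5. The processed signal in these files was already background-subtracted and detrended within the array by that software, not normalized between arrays, and the mean spot signal and local background stand beside it. Per the file headers the probe coordinates are in the mm7 build. The deposited value table of the series was identical to the processed signal of the scanner files, with a largest difference of 0, so its scale is linear, it is not centred, and its columns have no ratio direction; its medians are 186 (185.5), 181 and 173 for control replicates 1, 2 and 3 and 167, 162 (161.8) and 173 (172.6) for BRG1 siRNA replicates 1, 2 and 3.

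From the intensities, log2 of the processed signal minus the 75th percentile of the non-control spots of each array was computed. Each array had 45018 spots, and the 1639 control spots were left out, as were spots the software marked as outliers on that array (387 spots on at least 1 array); saturated spots, 0 to 2 per array, were kept. Spots of a probe were averaged, and each gene name was represented by the probe with the highest mean signal. A gene was tested if that probe was well above background on every array of at least 1 group, which left 17758 of 27962 gene names. Among changed genes 1588 had another tested probe; for 615 of these another probe passed the test in the same direction and for 13 in the opposite direction. Probes above background in only 1 group carry a bound instead of a fold, from the higher of the dim probe's own signal and the lowest signal well above background on each array. Names were updated by RefSeq accession through an annotation table of the GRCm38.p6 assembly, used for names only: 11920 of the tested genes matched by accession, 1765 by symbol, and 4073 kept the name in the file.

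Groups were compared with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The 31 gene lists, the rule for named genes, the tests of the comparison and the alternatives were fixed before the data were examined, apart from spike-in scaling, which was chosen after seeing the data; tests that weigh explanations are separate, and those chosen after the result was seen are named beside them. Lists with at least 5 tested genes were tested with camera at a preset inter-gene correlation of 0.01; an estimated correlation and fry were alternatives. A gene of the two-cell-like list under an older and a newer symbol was counted once, a correction made after the values were seen. The named genes are Smarca4 with every probe; the 10 raised and 10 lowered genes with the largest change among those past the threshold, well above background on all 6 arrays, without overlap between groups and with a known symbol; up to 3 genes per direction with the largest bound, of which 0 were raised; up to 4 members past the threshold with the largest change of each called list and of the lineage, pluripotency, SWI/SNF, p53, interferon and fibroblast lists; and Pou5f1, Sox2, Nanog and Smarca2. The rule takes 76 genes, most of which are given, and the few named outside it are marked where they stand.

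The alternatives were normexp background correction (offset 50) with quantile or 75th percentile normalization, quantile normalization, median scaling, other filters on dim probes, slide as a fixed or random block, slide 1 alone, the replicate number as a block, other probe summaries, eBayes with trend and robust, array weights, the deposited value table, and each array left out in turn. The scan followed the same split as the slide, so both are 1 batch here. No 2 arrays held copied data: at most 1 spot had the same value on 2 arrays. The SD of log2 differences between arrays of a group ran from 0.232 to 0.320. No known technical repeat was at hand for comparison, so repeats of 1 RNA sample are not excluded. The method was tested on simulated data with 17758 genes, 200 of them changed. There it recovered 22% of changes of 1.25-fold, 46% of 1.5-fold, 80% of 2-fold and 88% of 4-fold, and called 2 unchanged genes. The adjusted threshold depends on how many genes change, and the real arrays gave 4139 calls, so these shares do not carry over. No slide effect was simulated. A simulated shift of the WNT list by -0.4 was called, with 0 of the other lists. The simulated noise was independent between genes, so this could not show false list calls from genes that vary together.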

Results

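Gene expression was measured in cultured mouse embryonic stem (ES) cells, pluripotent cells taken from the early embryo, after 48 h with a scrambled control siRNA or with an siRNA against BRG1. BRG1, encoded by Smarca4, is the ATPase that drives SWI/SNF complexes, which move and evict nucleosomes. Each group held 3 arrays, and labelled RNA made from 500 ng of total RNA was hybridised to single-colour Agilent arrays with 41174 probes for 27962 gene names. The share of spots well above background was 75.3%, 64.8% and 69.2% on control replicates 1, 2 and 3, and 65.5%, 60.9% and 70.9% on BRG1 siRNA replicates 1, 2 and 3. A total of 17758 genes were well above background on every array of at least 1 group and were tested. The labels do not say whether replicates came from separate cultures, so p-values measure the spread between these arrays, which may be technical, and the number of arrays limits the precision.

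The first question was whether the siRNA lowered its target. All 3 Smarca4 probes fell on all 3 BRG1 siRNA arrays. The probe used for the gene, on chromosome 9 at 21520316 to 21521714 of the mm7 build, plus strand, fell from a log2 signal of 4.30 ± 0.07 (SD, n = 3) in controls to 3.70 ± 0.09 (SD, n = 3), both relative to the 75th percentile of the array. That change of -0.60 ± 0.06 (SE, log2) left 65.8% of the control signal (limma adjusted p = 0.00365). The probe at 21582352 to 21582411 showed 54.7% of the control signal (adjusted p over probes = 0.00181), and the dimmer probe at 21514928 to 21514987 showed 66.2% (adjusted p over probes = 0.00861). No exon annotation of mm7 was used here, so the probes are placed by coordinate only. The arrays lay on 2 slides, with the 3 control arrays and BRG1 siRNA replicate 1 on slide 1 and BRG1 siRNA replicates 2 and 3 on slide 2. With slide as a block the change was -0.54 (adjusted p = 0.0425), and with slide 1 alone, where a single BRG1 siRNA array faces the controls, the same -0.54 did not pass the test (adjusted p = 0.0724).

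**Figure D1:**
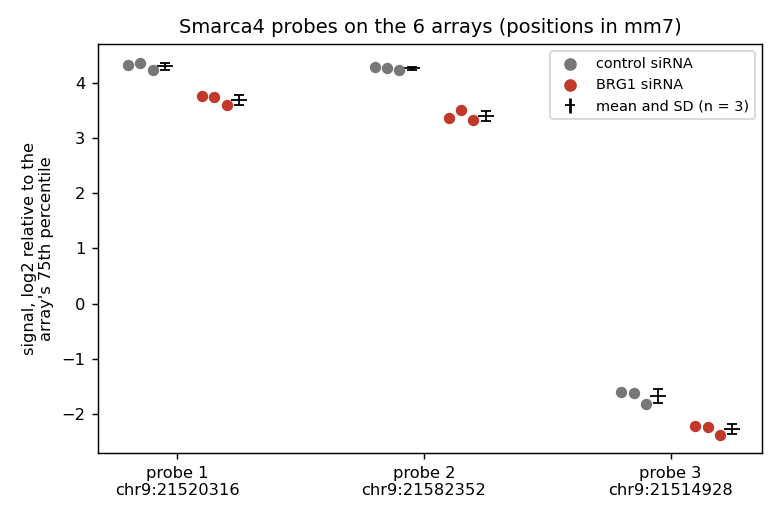
Signal of the 3 Smarca4 probes on the 6 arrays, as log2 relative to the 75th percentile of each array (y axis), with probes on the x axis by their start on chromosome 9 of mm7. Gray points are control siRNA arrays, red points BRG1 siRNA arrays, and black bars the mean with SD (n = 3). All BRG1 siRNA points lie below all control points of the same probe, with means of 3.70 against 4.30 for the probe used.

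The second question was which genes changed when BRG1 was reduced. BRG1 siRNA raised 1752 genes and lowered 2387, together 4139 of the 17758 tested (limma, Benjamini-Hochberg adjusted p under 0.05). Most changes were small: 3433 of these genes moved by less than 1.5-fold, the median rise was 1.24-fold and the median fall 1.27-fold. At least 2-fold changes were seen for 33 raised and 102 lowered genes. The groups did not overlap for 44.0% of the genes tested, where chance gives 10% for 3 arrays against 3. Leaving out any array other than BRG1 siRNA replicate 3 lowered the count by more than 1.5 times, to 2556, 1953 and 1641 without control replicates 1, 2 and 3 and to 2283 and 2015 without BRG1 siRNA replicates 1 and 2. Slide as a block gave 1392 genes, 477 of them raised, with 1292 among the 4139, and slide 1 alone gave 59, with 25 among them. The 42.3% share of rises among changed genes became 84.6% with scaling on spike-in probes, which moved the median of all genes to 0.16 (log2), and directions below are relative to the 75th percentile of each array.

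**Figure D2:**
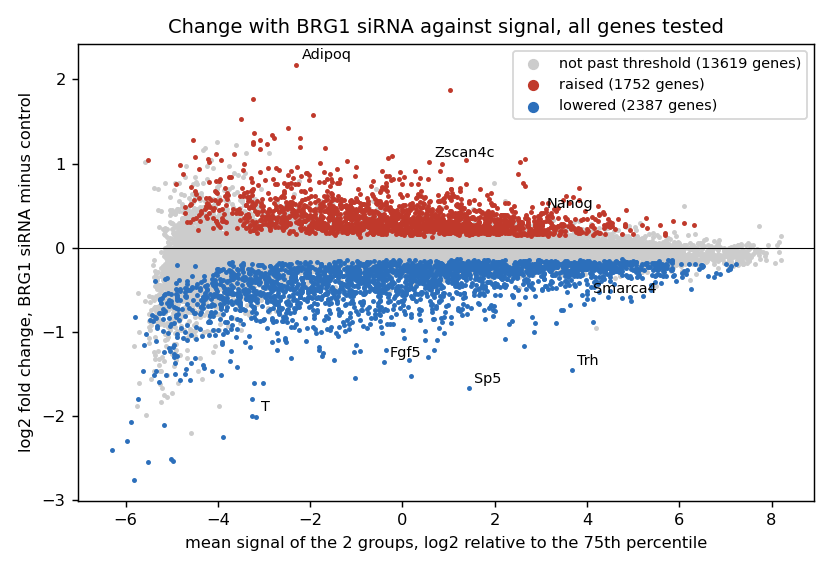
Change with BRG1 siRNA (y axis, log2 fold change) against mean signal of both groups (x axis, log2 relative to the 75th percentile) for the 17758 genes tested. Red points are the 1752 raised genes, blue points the 2387 lowered genes and gray points genes that did not pass the test; falls of at least 2-fold, 102 genes, outnumber rises of that size, 33 genes.

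T, the brachyury transcription factor of the primitive streak, was 4.02-fold lower with BRG1 siRNA (log2 -2.01 ± 0.15 SE, adjusted p = 0.00167), and Sp5, a transcription factor induced by WNT signalling, was 3.18-fold lower (-1.67 ± 0.10, adjusted p = 0.00114). Fgf8, a growth factor of the streak, was 2.92-fold lower (-1.55 ± 0.18, adjusted p = 0.00465). Tgtp1, an interferon-inducible GTPase whose probe may also detect close family members, fell 3.99-fold, and Zbp1, a sensor of unusual nucleic acids, fell 3.48-fold. Trh, the precursor of thyrotropin-releasing hormone, was bright in controls (log2 4.39 ± 0.10 SD, n = 3) and fell 2.75-fold, and the glutathione peroxidase gene Gpx2 fell 2.87-fold. Cd79b, a B cell receptor component, Prl2c5, of the prolactin family, and Myo3b, a myosin, fell 3.05-fold, 3.05-fold and 2.67-fold. On BRG1 siRNA arrays T, Tgtp1, Zbp1, Cd79b, Prl2c5 and Myo3b were dim, at -4.29 to -3.83 (log2), where folds depend on the background correction. Sp5, Fgf8, Gpx2 and Trh were brighter there, at -1.80 to 2.94. At least 2-fold falls numbered 32 with normexp under either normalization, against 102. The call for Myo3b was lost with slide as a block (log2 -1.19) and without control replicate 2 or 3. When its probes were averaged the change was 0.023. Krt23, Maob and Txlnb were not well above background on any BRG1 siRNA array and were at least 2.30-fold, 2.43-fold and 2.23-fold lower (adjusted p = 0.0042, 0.00417 and 0.013); each bound sets the controls against the higher of the probe's own signal and the lowest signal counted as well above background on each BRG1 siRNA array. The call for Txlnb was lost without control replicate 3 or BRG1 siRNA replicate 2.

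Among rises, Adipoq, which encodes the fat cell hormone adiponectin, led with 4.51-fold (log2 2.17 ± 0.10 SE, adjusted p = 0.000803). The PRAME-like family members Pramel37 and Pramel39, close relatives whose probes may cross-detect, rose 3.40-fold and 2.88-fold. Pdzd2, a PDZ domain protein, rose 3.00-fold (1.58 ± 0.05, adjusted p = 0.00044), Adra1b, an adrenergic receptor, 2.54-fold, and Cxcl11, an interferon-inducible chemokine, 2.44-fold. Zscan5b, Prom2, Spag6l and Cibar2 rose 2.39-fold, 2.35-fold, 2.48-fold and 2.58-fold. These 10 genes were dim in controls, at -4.25 to -2.73 (log2), where folds depend on the background correction. With normexp, 14 (quantile) and 12 (75th percentile) genes rose at least 2-fold, against 33. With slide as a block the calls for Adra1b, Spag6l and Cibar2 were lost, Cibar2 was also lost without control replicate 2 or 3, and Pdzd2 and Prom2 were lost when the probes of a gene were averaged.

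**Figure D3:**
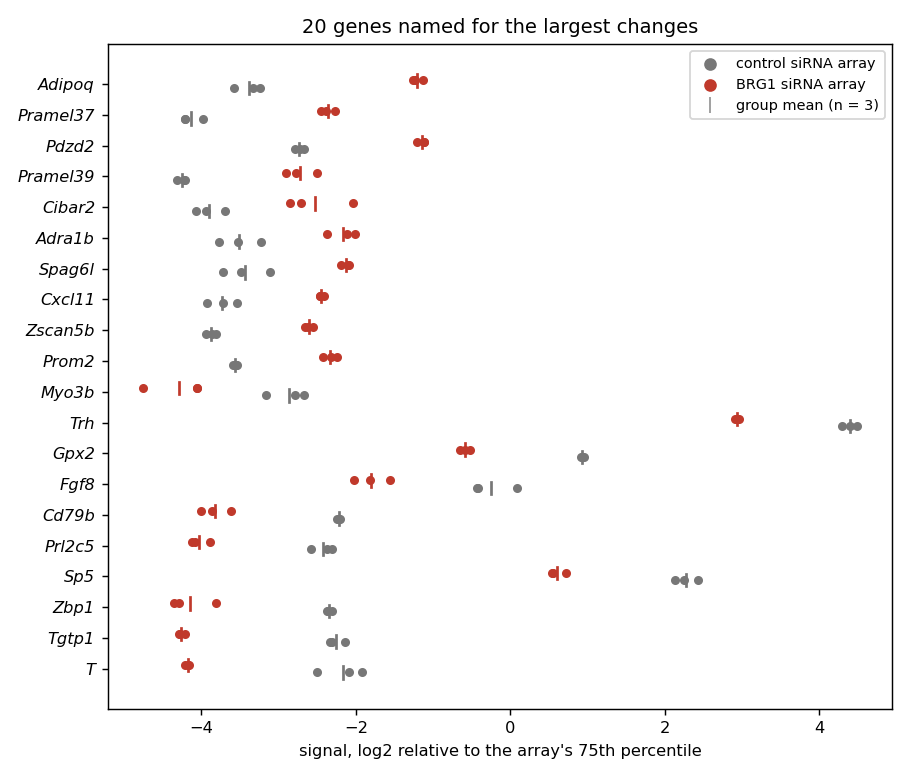
Signal on each array (x axis, log2 relative to the 75th percentile) for the 10 raised and 10 lowered genes named for the largest changes (y axis). Gray points are control siRNA arrays, red points BRG1 siRNA arrays, and vertical ticks group means (n = 3); the groups are separate for every gene shown, from Adipoq, 4.51-fold higher, to T, 4.02-fold lower.

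Genes downstream of WNT signalling fell as a group. Of 15 tested WNT target genes, 11 fell and none rose, and 12 fell when adjusted over the list alone, with a median log2 change of -0.41 (camera adjusted p = 2.25e-06; adjusted p = 0.261 with an estimated correlation). Besides T and Sp5, Lef1, a transcription factor that mediates WNT signals, was 2.02-fold lower (-1.02 ± 0.11, adjusted p = 0.00387), Cdx2, a caudal homeobox factor, was 1.93-fold lower. Axin2, a feedback inhibitor of the pathway that was chosen after its values were seen, fell 1.66-fold, and the Lef1 call was lost when its probes were averaged. Cdx1 also fell, with no fold given since it was well above background on 1 of the 3 BRG1 siRNA arrays, and its call was lost without control replicate 2 or 3 or BRG1 siRNA replicate 2. With slide as a block, which equals the value within slide 1, the median was -0.43 (camera adjusted p = 1.99e-05), and with spike-in scaling it was -0.21. Of these genes, 6 were also members of other lists.

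Post-implantation epiblast genes, active in the embryo's pluripotent tissue after implantation, fell too: 8 of 15 fell, 10 when adjusted over the list alone, and none rose, with a median of -0.38 (camera adjusted p = 0.000622; adjusted p = 0.198 with an estimated correlation) and -0.26 with slide as a block (camera adjusted p = 0.00894), -0.18 with spike-in scaling and -0.23 with the mean over probes. Fgf5, the growth factor that marks this tissue, was 2.56-fold lower (-1.36 ± 0.14, adjusted p = 0.00314), the homeobox gene Otx2 1.79-fold and the kinase gene Pim2 1.69-fold; the call for Otx2 was lost with slide as a block. Streak, mesoderm and definitive endoderm markers moved both ways, with 4 of 22 raised and 5 lowered, and 4 and 7 when adjusted over the list alone (camera adjusted p = 0.373). Fgf8, T, Sp5 and Wnt3 (1.78-fold) fell, whereas Hand1, a mesoderm and trophoblast factor, rose 1.73-fold. Fibroblast markers moved with these groups: 10 of 24 fell and 2 rose, 11 and 2 when adjusted over the list alone, with a median of -0.23 (camera adjusted p = 0.0331; adjusted p = 0.303 with an estimated correlation). S100a4 and Thy1 fell 2.12-fold and 1.73-fold, and Mgp and Lox rose 2.25-fold and 1.68-fold. With spike-in scaling the fibroblast median was -0.03 (-0.0273). The call was lost with slide as a block (median -0.20, camera adjusted p = 0.127), without control replicate 2 (camera adjusted p = 0.113) and without BRG1 siRNA replicate 3 (camera adjusted p = 0.0707).

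Cholesterol synthesis genes fell, with the fibroblast markers at -0.23 beside them. Of 24 tested members 12 fell, 15 when adjusted over the list alone, and none rose, and the median was -0.24 (camera adjusted p = 1.73e-05; adjusted p = 0.176 with an estimated correlation). Insig1, a regulator of sterol synthesis, fell 1.34-fold (-0.42 ± 0.07, adjusted p = 0.0111), and Fdps, an enzyme of the pathway, fell 1.32-fold (-0.41 ± 0.07, adjusted p = 0.0113). With slide as a block the list kept a median of -0.25 (camera adjusted p = 0.000322), but the single calls for Insig1 and Fdps were lost. With spike-in scaling the median was -0.04 (-0.0372, camera adjusted p = 0.000261), and the calls for Insig1 and Fdps were lost with spike-in or median scaling. The Insig1 call was also lost without BRG1 siRNA replicate 2 and the Fdps call without control replicate 3.

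Genes of the two-cell-like state, a rare ES cell state that resembles the embryo after its first division, rose. Of 7 tested genes, 4 rose and none fell, the same counts as when adjusted over the list alone, with a median of 0.47 (camera adjusted p = 0.00428; adjusted p = 0.387 with an estimated correlation) and 0.44 with slide as a block (camera adjusted p = 0.0083). The median was 0.23 without control replicate 2 (camera adjusted p = 0.0191) and 0.29 with the mean over probes (camera adjusted p = 0.00879), with the list called each time. Zscan4c, a zinc finger gene that marks this state, rose 2.03-fold (1.02 ± 0.06, adjusted p = 0.00136), Usp17la 1.83-fold and Tcstv3 1.41-fold. Tcstv1 rose 1.39-fold, a call lost with slide as a block and without any array except control replicate 1, and the Tcstv3 call was lost when its probes were averaged. The Zscan4, Usp17 and Tcstv genes have near-identical copies, so these probes may read several of them. Germ line genes showed 8 rises and 2 falls among 20, 8 and 3 when adjusted over the list alone, with a median of 0.22 (camera adjusted p = 0.0319; adjusted p = 0.622 with an estimated correlation) and 0.15 with slide as a block (camera adjusted p = 0.0498). Hormad1, a meiotic chromosome protein, rose 1.59-fold, the meiotic cohesin gene Stag3 1.46-fold, the germ cell helicase gene Ddx4 1.44-fold and Mael, a gene of transposon silencing, 1.42-fold. With spike-in scaling the germ line median was 0.42. The germ line call was lost with quantile normalization, spike-in scaling and slide 1 alone (camera adjusted p = 0.0521, 0.065 and 0.0596), and over the camera settings run with the preset correlation its lowest adjusted p was 0.00856.

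**Figure D4:**
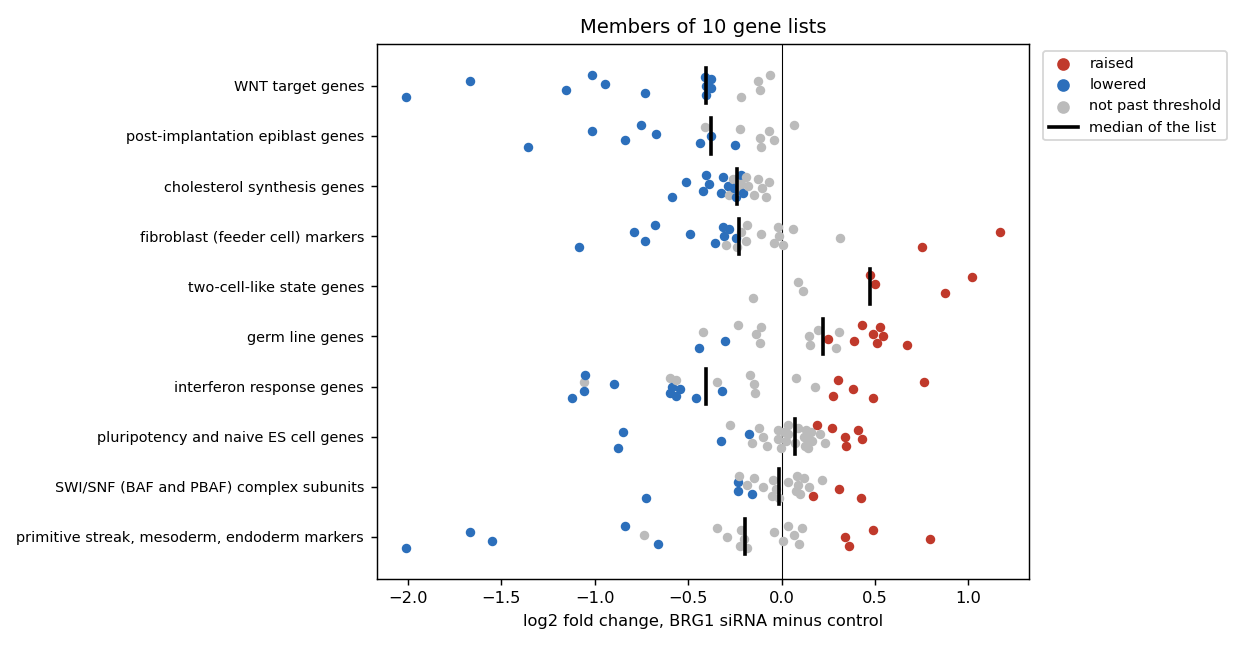
Members of 10 gene lists (y axis) by log2 fold change with BRG1 siRNA (x axis). Each point is a tested gene, red if raised, blue if lowered and gray if it did not pass the test, and the black bar is the median of the list; WNT target genes have a median of -0.41 and two-cell-like state genes of 0.47.

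Pluripotency genes moved both ways. Of 33 tested pluripotency and naive ES cell genes, 6 rose and 4 fell, 8 and 5 when adjusted over the list alone (camera adjusted p = 0.131). Lefty1 and Lefty2, inhibitors of NODAL signalling, fell 1.84-fold and 1.80-fold. Nanog rose 1.33-fold (0.41 ± 0.07, adjusted p = 0.0138), Utf1 rose 1.35-fold and Pou5f1 fell by 0.33 ± 0.06 (log2, adjusted p = 0.0206). Sox2 did not pass the test (-0.16 ± 0.04, adjusted p = 0.0521), and with spike-in scaling its sign turned, to 0.0403. The Nanog call was lost with slide as a block, with median scaling and without control replicate 3 or BRG1 siRNA replicate 1, the Utf1 call with median scaling and without any array except BRG1 siRNA replicate 3, and the Pou5f1 call with slide as a block, with median, quantile or spike-in scaling, and without control replicate 2 or 3 or BRG1 siRNA replicate 2.

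Other subunits of SWI/SNF moved both ways. Of 23 tested, 3 rose and 4 fell, 4 and 4 when adjusted over the list alone (camera adjusted p = 0.677). Arid1a, a DNA-binding subunit, rose 1.34-fold (0.43 ± 0.04, adjusted p = 0.003). Smarca2, which encodes BRM, the alternative ATPase, fell 1.65-fold (-0.73 ± 0.08, adjusted p = 0.00431) at a signal near background, well above it on 2 of the 3 BRG1 siRNA arrays, and the call was lost with quantile normalization and when its probes were averaged. Bcl7a rose 1.24-fold and Brd7 fell 1.18-fold; both calls were lost with slide as a block, that for Brd7 also with every other scaling run, that for Bcl7a without control replicate 2 or 3 or BRG1 siRNA replicate 1, and that for Brd7 again without any array except BRG1 siRNA replicate 3. Among other ATP-dependent remodelers, 3 of 18 rose and 2 fell, 3 and 4 when adjusted over the list alone (camera adjusted p = 0.718). The camera direction was up where the SWI/SNF median and mean lay below 0 (-0.0157 and -0.0168) and where the remodelers had a median of 0.0225 and a mean of -0.0465.

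Interferon response genes changed in both directions: 10 of 24 fell and 5 rose, 13 and 6 when adjusted over the list alone, with a median of -0.40, and the list was not called (camera adjusted p = 0.103). It was called with spike-in or median scaling (camera adjusted p = 0.000794 and 0.017), with normexp and quantile normalization (0.044), with no filter on dim probes (0.0325), with every probe on its own (0.0196) and without control replicate 1 (0.0377), and over the other preset-correlation settings its highest adjusted p was 0.187. The median was -0.20 with spike-in scaling, -0.26 with normexp and quantile normalization and -0.24 for genes well above background on all 6 arrays. Oasl2, Isg15 and Psmb8 fell 2.17-fold, 2.08-fold and 2.07-fold, and Irf1, an interferon-induced transcription factor, fell 1.86-fold (-0.90 ± 0.06, adjusted p = 0.00147). With slide as a block the median was -0.35 (camera adjusted p = 0.144). Blood and immune cell markers, 1 raised and 0 lowered of 12, with the same counts when adjusted over the list alone, had a median of -0.075 (camera adjusted p = 0.948). The raised marker, Cd68, was chosen after its values were seen and rose 1.39-fold.

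For p53 target genes, 3 of 27 rose and 4 fell, with the same counts when adjusted over the list alone (camera adjusted p = 0.948); Tap1, a peptide transporter, rose 1.52-fold, the polymerase gene Polk 1.43-fold, and Ddit4 and Perp fell 1.29-fold and 1.26-fold, both lost with slide as a block and with median or spike-in scaling, Ddit4 also without control replicate 2 or 3 or BRG1 siRNA replicate 2. Trophectoderm markers showed 3 rises and 6 falls among 19, 4 and 6 when adjusted over the list alone (camera adjusted p = 0.821), with Rhox6 2.33-fold and Krt7 1.73-fold lower. Primitive and visceral endoderm markers showed 1 rise and 6 falls among 21, the same when adjusted over the list alone (camera adjusted p = 0.291), with the collagen chaperone gene Serpinh1 1.67-fold, Lama1 1.46-fold, Plat 1.40-fold and Dab2 1.49-fold lower; the Lama1 call was lost with slide as a block, both the Lama1 and the Plat call with spike-in scaling, and the Dab2 call with slide as a block and without any array except control replicates 1 and 2. Neural markers showed 1 rise and 6 falls among 22, 2 and 7 when adjusted over the list alone (camera adjusted p = 0.275), with Hes5, a NOTCH target, 1.82-fold and Sox11 1.30-fold lower. The Hes5 call was lost with slide as a block and the Sox11 call with median or spike-in scaling and without control replicate 2 or 3 or BRG1 siRNA replicate 2. Map2 was 1.28-fold lower and Ncam1 1.19-fold higher. Both calls were lost with slide as a block, with median scaling and without any array except BRG1 siRNA replicate 3 for Map2 and control replicate 1 for Ncam1. Endothelial markers showed 0 rises and 4 falls among 9, the same when adjusted over the list alone (camera adjusted p = 0.291).

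The other lists were not called, and their counts follow as rises and falls over all genes and then adjusted over the list alone. Cyclins and CDK inhibitors had 2 and 8 of 20, then 2 and 10 (camera adjusted p = 0.0805). Imprinted genes had 1 and 8 of 23, then 3 and 9, and glycolysis and hypoxia genes 2 and 7 of 23, then 2 and 10 (camera adjusted p = 0.0805 for each). Polycomb subunits had 7 and 3 of 27, then 8 and 5 (camera adjusted p = 0.0805). Ribosomal protein genes had 0 and 0 of 39 by limma, both ways, with 5 at an unadjusted p under 0.05 (camera adjusted p = 0.0805), and the list was called with slide as a block (median -0.17, camera adjusted p = 0.00534). It was also called with slide 1 alone, with no filter on dim probes, with every probe on its own and without BRG1 siRNA replicate 3. Cyclins and CDK inhibitors and imprinted genes were called with no filter, with the mean over probes, with every probe on its own and without control replicate 1. The cyclins were also called with normexp and 75th percentile scaling, and the imprinted genes without BRG1 siRNA replicate 1. Glycolysis genes were called with no filter and without control replicate 1, and the stress genes without control replicate 1. Stress genes of the integrated and endoplasmic reticulum response had 1 and 8 of 21, then 1 and 9 (camera adjusted p = 0.213), proliferation genes 1 and 8 of 31, then 2 and 9 (0.274), and heat shock genes 1 and 2 of 10, both ways (0.456). BMP and TGF-beta targets had 4 and 5 of 19, then 4 and 7 (0.611), HOX genes 0 and 1 of 18, both ways (0.677), and adhesion and epithelial-mesenchymal transition genes 5 and 7 of 23, then 8 and 8 (0.889). Apoptosis regulators had 2 and 5 of 27, then 2 and 6 (0.917), LIF-STAT3 targets 3 and 3 of 20, then 4 and 3 (0.948), and ERK-FGF feedback genes 2 and 4 of 18, both ways (0.98). The 6 list calls did not hold with an estimated correlation, where 0 of the 31 lists passed and 4 had an unadjusted p under 0.05; fry, which asks whether the genes of a list move on balance 1 way, passed 18. Signs of median, mean and camera direction also differed for the adhesion list (-0.00119, -0.0481 and up), the LIF-STAT3 list (-0.0179, -0.0352 and up) and the p53 list (-0.0199, 0.00171 and up).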

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

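The tests of the scanner's background correction, of scaling on spike-in probes, of the slide and of all explanations for the interferon genes were chosen only after the result was seen. Spike-in probes, control RNA that is added at a fixed amount and used above only as an alternative scaling, gave a difference between groups. The 75th percentile of the array lay at -2.85 ± 0.10 (SD, n = 3, log2) relative to the spike-in probes on BRG1 siRNA arrays and at -3.04 ± 0.08 (SD, n = 3) on control arrays, a difference of 0.20 with every BRG1 siRNA array above every control array. An exact two-sided permutation test gave p = 0.1, the smallest that 3 arrays against 3 allow. Whether the cells or the amounts of RNA and spike-in differed was not tested.

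Falls of at least 2-fold outnumbered rises, 102 to 33. The background correction of the scanner software as the whole cause is argued against by normexp with 75th percentile scaling, where the ratio of falls to rises was 2.67 (32 to 12). With normexp and quantile normalization the counts were 32 and 14. Both settings left far fewer falls than 102, so the ratio cannot show how much of the excess came from that correction. Scaling of the arrays stays open: with spike-in scaling the ratio was 0.66 (60 to 91), but that scaling moves all genes of an array alike, so the turn follows from the shift and does not show which level is right. Signal near background also stays open: among genes above the 75th percentile the ratio was 2.6 (13 to 5), with an exact two-sided binomial p of 0.0963. With genes in 5 bins of signal, the lowest bin held 57 of the 102 falls and 8 of the 33 rises. Falls also outnumbered rises in each brighter bin, by 22 to 17, 13 to 3, 7 to 3 and 3 to 2. Genes well above background on all 6 arrays gave 53 falls and 30 rises. All genes of the lowest bin had a median log2 change of -0.16, against -0.055 to 0.017 in the other bins. Tested genes with no probe well above background on any BRG1 siRNA array numbered 60, with 40 lowered past the threshold. For control arrays the number was 0, so the filter on dim probes let in such genes on the side of falls only. Much of the excess thus lay among dim genes, and signal near background may account for that part. A direct effect of less BRG1 was not tested apart from these.

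WNT target and epiblast genes fell together. A slide effect as the whole cause is argued against by the WNT median of -0.43 on the slide that holds both groups and by 10 of the 11 falls, which passed with slide as a block too, although these values rest on 1 BRG1 siRNA array there. Fewer differentiating cells in the BRG1 siRNA cultures may account for the pattern: of 12 tested streak markers outside both lists, 3 fell (Fgf8, Wnt3 and Eomes, at -0.25, -0.27 and -2.38 in controls, log2) and 1 rose (Hand1), a difference of 2 and exactly the 3 to 1 set in advance as the least ratio. Of the other 8, none passed. Mesp1, Foxa2, Kdr and Tbx6 changed by 0.07, 0.03, 0.11 and -0.04, against a general loss of such cells. Cxcr4, Lhx1, Evx1 and Gsc leaned the other way without passing, at -0.74, -0.29, -0.22 and -0.20. The set of markers was fixed in advance, but Eomes and these 8 lie outside the naming rule and were named after their values were seen. Mesp1, Cxcr4, Hand1, Gsc and Lhx1 were dim in controls, at -3.87, -4.86, -4.45, -3.75 and -3.58, and the explanation stays open. Lower WNT signalling in unchanged cell types remains an untested hypothesis.

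More interferon response genes fell than rose, 10 to 5, with a list that was not called. A slide effect as the whole cause is argued against by the median of -0.35 on the slide that holds both groups and by 8 of the 10 falls, which passed with slide as a block too, as did 1 of the 5 rises; these values also rest on 1 BRG1 siRNA array there. Fewer blood or immune cells could not be ruled out, since the median of their markers was -0.075 with a lower quartile of -0.36 and most of them lay near background; the brightest, Laptm5 and Cd68, stood at -1.31 and -1.34 in controls. A response to the control siRNA could also give this pattern by raising the genes in controls, and 0 of the arrays analysed here had no siRNA or another control siRNA. An effect of less BRG1 itself was not tested apart from these.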

How the results depend on the processing

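Spike-in scaling was the setting chosen only after the result was seen. Smarca4 fell past the threshold under every setting run except slide 1 alone (-0.54, adjusted p = 0.0724), and its log2 change ran from -0.40 (spike-in scaling) to -0.69 (mean over probes); with each array left out in turn it ran from -0.55 to -0.64, past the threshold each time. The counts of genes changed, genes raised and genes lowered moved by over 1.5 times with median scaling (1734, 833 and 901), no filter on dim probes (1740, 697 and 1043), slide as a block (1392, 477 and 915), slide 1 alone (59, 37 and 22), the mean over probes (2585, 1115 and 1470) and array weights (8214, 3395 and 4819); with spike-in scaling 3613 were raised and 656 lowered. Slide 1 alone has fewer arrays, and no filter tests more genes; the cause of the other moves was not tested. Genes changed at least 2-fold numbered 46 and 44 with normexp (quantile and 75th percentile), 83 when well above background on all 6 arrays, 59 on slide 1 alone and 235 with array weights. The 6 gene lists called became 11 with no filter, 10 with every probe on its own, 18 with fry, which does not compare a list with other genes, and 0 with an estimated inter-gene correlation. Leaving out each array in turn gave 1641 to 4415 genes changed, 681 to 1739 raised, 960 to 2676 lowered, 105 to 190 at least 2-fold and 5 to 11 lists. Myo3b turned to 0.023 with the mean over probes and Sox2 to 0.0403 with spike-in scaling.

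The arrays gave no sign of pairing by replicate number: deviations of same-numbered arrays correlated at -0.31, 0.11 and -0.02. Not every array correlated best with its own number. Deviations from means of 3 arrays cannot show that the samples were unpaired. The replicate block gave 1945 genes changed, 788 raised and 1157 lowered, with 114 at least 2-fold and 6 lists. Of 75 named genes past the threshold, 55 stayed past it with slide as a block, 63 with median scaling, 65 with spike-in scaling and 12 on slide 1 alone. Of 10 splits of the 6 arrays into 3 and 3, 1 (the real one) gave as many genes changed, raised, lowered or changed at least 2-fold, with real values of 4139, 1752, 2387 and 135 and 3 as the highest other for each, since a split and its mirror count as 1 and a gene lowered in a split is raised in its mirror. For gene lists called, 3 splits, the real one included, gave at least 6. The highest other, 11, put both slide 2 arrays with control replicate 1, and with slide as a block the real split gave 6. The next, 10, mixed the slides, with BRG1 siRNA replicates 1 and 3 beside control replicate 1. Both put control replicate 1 with BRG1 siRNA replicate 3, the arrays with most spots well above background (75.3% and 70.9%). Splits that put these arrays with control replicate 2 or 3 called only 2 and 3 lists. What made any of these splits call lists was not tested. So few splits cannot give a share under 0.05. Signal over background limits the dim genes: with genes in 5 bins of signal the median residual SD was 0.277 (log2) in the lowest and 0.0568 in the highest.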

Other observations

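A total of 8 families were chosen after their values were seen, so their values are given without a test of the family. Of 8 tested guanylate-binding protein genes, which act in defence against intracellular pathogens, 5 fell and none rose (median -0.79), with Gbp2b 1.87-fold and Gbp3 1.81-fold lower and Gbp4, well above background on 2 of the 3 BRG1 siRNA arrays, 4.75-fold lower. Of 14 major histocompatibility complex class I genes, which present peptides to T cells, 11 fell and none rose (median -0.28), with H2-K1 1.61-fold and H2-T23 1.35-fold lower. Irgm1, an immunity-related GTPase, fell 2.36-fold, 1 of 3 that fell among 4 in its family (median -0.87). Medians on the slide that holds both groups were -0.74, -0.29 and -0.81 for these 3 families. With spike-in scaling the class I median was -0.081, and with median or spike-in scaling 3 of 14 class I genes, 3 of 8 guanylate-binding protein genes and 2 of 4 immunity-related GTPases fell past the threshold. The guanylate-binding median was -0.37 with normexp and quantile normalization and -0.40 with normexp and 75th percentile scaling. Some members of these families are close relatives, so a probe may read more than 1 of them. Not all probes moved alike: Igtp changed by -0.04 (log2) against -1.24 for Irgm1, and Gbp5 by -0.09.

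Of 5 tested PRAME-like genes, 3 rose and none fell (median 0.56), and Pramel37 and Pramel39 were already among the largest rises. Sox genes (2 raised and 1 lowered of 16) and Trim genes (7 raised and 5 lowered of 41) moved both ways. With spike-in scaling 5 Sox genes rose and 0 fell, and 12 Trim genes rose and 2 fell. Of 24 keratins 6 fell and none rose, but with spike-in scaling 4 rose and 5 fell, and of 22 serpins 8 fell and 1 rose, against 6 and 4 with spike-in scaling.

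Single genes outside the naming rule, also chosen after their values were seen, included Cdkn2a, which encodes inhibitors of proliferation and fell 2.15-fold, Ccnd2, which fell 1.74-fold, and the Polycomb gene Bmi1, which rose 1.93-fold. Nodal, a signalling ligand, rose 1.26-fold.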
